A study of Mus musculus with 10 samples.

How the data were processed

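The series holds 10 arrays of mouse liver RNA, 1 per sample, extracted from 25 mg of tissue. The deposited values are log2 expression values per transcript cluster, a group of probes for one transcript region, and per the submitters' processing notes they were made with Affymetrix Expression Console. Its version, the background correction, the normalization method and the genome build are not given in the sources used here. The log2 scale was read from the values, which ran from 1.40 to 13.8 with array medians of 4.06 to 4.17. There is 1 colour, no reference channel and no pooling of samples. The values were used as deposited, so that any effect of the unstated normalization is carried into the results. No 2 arrays held identical values.

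Of 41345 transcript clusters, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none there. Of those with 1 symbol, 23328 matched the gene table of assembly GRCm38.p6 by Entrez identifier, which changed 0 symbols. Clusters with several or no symbols were tested only by themselves, as an alternative. For a gene with more than 1 cluster, which was so for 1082 genes, the cluster with the highest mean was kept, leaving 22180 genes. Genes below the 40th percentile of mean level (log2 3.98) were left out, leaving 13308. Members of families with near-identical sequence, such as Mup, Cyp2b and Gst genes, were not told apart beyond this annotation. No build is named, so no coordinates are given, and the gene table was used only for names and for which genes neighbour each other.

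Groups were taken from the sample titles: 4 rtTA controls, 3 shRNA 1 and 3 shRNA 2 livers. One limma fit over all 10 arrays (lmFit, contrasts.fit and eBayes; limma 3.58.1 in R 4.3.3) gave 4 comparisons: the mean of both shRNA groups against control, each group against control, and shRNA 1 against shRNA 2. Cohort was no covariate, since the labels do not assign the controls to cohorts. P-values were adjusted by the Benjamini-Hochberg method over the 13308 genes, with a threshold of 0.05, and all tests were two-sided. Exact permutation tests of 6 against 4 samples ran over all 210 splits, so the smallest p is 0.0048. Before the data were examined, 57 gene and cell type lists were fixed, and the 50 with at least 5 measured members were tested with camera at the preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and the directional fry test were run beside it. List means per sample are relative to the mean of the controls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

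The rule for named genes was fixed at the same time. For the adapted comparison it took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, filled with the smallest unadjusted p and then given as values only. For the other comparisons it took 5 in each direction, and for each list up to 4 members with the largest absolute moderated statistic in adapted against control. Sod2 was always named. Symbols of predicted, unnamed and small noncoding genes were passed over among the top genes.

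The fit was tested on simulated data with the real means and spread of the 13308 genes, of which 200 were shifted in each of 10 runs. For adapted against control it recovered 70.0% of genes shifted by 0.5 on the log2 scale and 99.1% of those shifted by 1, with 5.08% of calls false. The recovery at 0.5 was 51.2% for shRNA 1, 47.9% for shRNA 2 and 35.8% for shRNA 1 against shRNA 2. With 200 shifted genes the adjusted threshold is easier to pass than in the real adapted comparison, where 1 gene passed. These shares are therefore not the power reached in the real data. The simulated genes were independent of each other, unlike the real ones. Under that condition camera called 0 unshifted lists in 10 runs, and it called a list shifted by 0.3 in 10 of 10.

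Alternatives were quantile normalization, median centring, no level filter or one at the 60th percentile, the mean of a gene's clusters, every cluster by itself, the replicate number as a block, array weights, an intensity trend with a robust prior, a fit with 2 groups or with only the groups compared, other thresholds, and leaving out each array in turn. A pseudocount planned for linear values was not needed. A covariate for the phase of the circadian clock, built from 9 clock genes, and a fit without 2 arrays were added after seeing the data.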

Results

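Gene expression was measured in livers of 4-week-old male mice on a whole-transcript Affymetrix mouse gene array, with 10 arrays in 3 groups. All animals carried rtTA, a transcription factor that switches on a linked construct when doxycycline is present. In 6 of them rtTA drove a short hairpin RNA (shRNA) against Sod2, the gene of the mitochondrial superoxide dismutase. The hairpin was shRNA 1 in 3 livers and shRNA 2 in 3 livers, and the other 4 livers came from littermates with rtTA alone. Dams received chow with doxycycline at 625 mg/kg, so that knockdown covered embryonic day 0 to 12.5, and the livers were collected long after that window. The 6 shRNA livers are called adapted here, after the term in the labels. The labels state that 3 controls belonged to the shRNA 2 cohort and 1 to the shRNA 1 cohort without saying which, so cohort could not be a term of the fit and, across genes, hairpin and cohort could not be separated. Means given by line are therefore unlike comparisons: that of shRNA 1 with control is mostly between cohorts, that of shRNA 2 mostly within 1 cohort. The labels number the liver samples without stating that each is a separate animal, so p-values measure the spread between these samples. Array medians lay between log2 4.06 and 4.17, and pairs of arrays correlated at 0.981 to 0.992 across genes. The number of arrays limits the precision of every comparison.

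The first question was whether the knocked-down gene was still low at 4 weeks. Sod2 was at log2 10.38 ± 0.08 (SD, n = 4) in controls, 10.39 ± 0.06 (SD, n = 3) in shRNA 1 livers and 10.35 ± 0.12 (SD, n = 3) in shRNA 2 livers. Adapted minus control was -0.01 with a standard error of 0.08, with an adjusted p of 0.980 in limma and p = 0.819 in an exact two-sided permutation test. All 10 values lay between 10.24 and 10.49. These values were taken after the doxycycline window, and the depth of the knockdown in utero was not measured on these arrays.

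**Figure D1:**
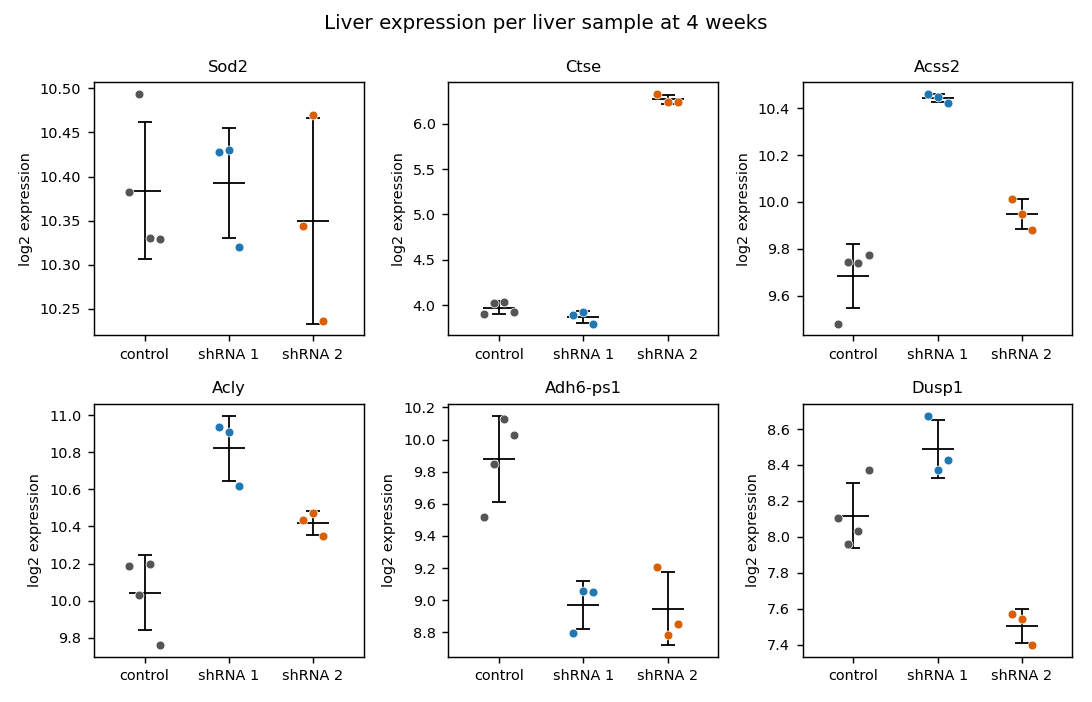
Log2 expression (y axis) of 6 genes in each liver sample by group (x axis); points are samples, horizontal bars are group means and error bars are 1 SD (n = 4, 3 and 3). Axes do not start at 0. Sod2 overlaps between groups, Ctse is near 4 in controls and shRNA 1 livers and above 6 in the 3 shRNA 2 livers, and all 6 adapted livers lie above the controls for Acss2 and Acly and below them for Adh6-ps1.

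Livers with either hairpin were compared with the rtTA controls to find what differed after the in utero knockdown. Of 13308 genes tested, 1 passed an adjusted p of 0.05 in limma: Ctse, encoding cathepsin E, an aspartic protease best known from gastric mucosa and blood cells, was higher by 1.10 on the log2 scale (standard error 0.07, adjusted p = 4.47e-05). The call came from one line: Ctse was at 6.27 ± 0.05 (SD, n = 3) in shRNA 2 livers against 3.97 ± 0.07 (SD, n = 4) in controls and 3.87 ± 0.07 (SD, n = 3) in shRNA 1 livers. It was above all controls in 3 of 6 adapted livers, the exact permutation p of 6 against 4 samples was 0.195, and the call was lost (adjusted p = 0.626) when the lines were fitted as a single group. Without control replicate 1 there were 3 calls and without control replicate 4 there were 2, and a filter at the 60th percentile of level left Ctse untested and 0 calls. At an unadjusted p under 0.05 there were 647 higher and 467 lower genes, against 665.4 of both kinds by chance, and 5 of 100 splits of the arrays, the real one included, gave at least as many genes past the adjusted threshold.

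The other genes that head the ranking are given as values, since none passed. They were picked by their p-values in these same arrays, so separation from all controls partly follows from that choice and is no added support. Among those with higher means in adapted livers were Acss2, which makes acetyl-CoA from acetate, at +0.51 (adjusted p = 0.158) and Acly, which makes it from citrate, at +0.58 (adjusted p = 0.170). Both were above every control in 6 of 6 adapted livers. Gstt1, a glutathione transferase, was at +0.57, Papss2, which makes the sulfate donor for sulfation, at +0.59, Retreg1, an endoplasmic reticulum autophagy receptor, at +0.56 and Dhrs7 at +0.55, each above all controls in 6 of 6. Trim12a (+0.52), Akr1c18 (+1.33) and the water channel Aqp8 (+0.72) completed the higher side. On the lower side Adh6-ps1, an alcohol dehydrogenase pseudogene, was at -0.93 with an adjusted p of 0.092 and lay below all controls in 6 of 6 adapted livers. Mup21, a major urinary protein, was at -1.26, Wdfy1, an endosomal adaptor, at -0.68, Atp5g1, a subunit of the ATP synthase ring, at -0.40 and Dhx37 at -0.42, each below all controls in 6 of 6. Cdc34 (-0.47), Tspan33 (-0.57), Apcs (-0.47), Pdilt (-0.53) and Scara5 (-0.57) followed. Adjusted p-values of all these genes except Adh6-ps1 lay between 0.158 and 0.264. With an intensity trend and a robust prior in limma, 6 genes passed instead of 1.

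Genes of fatty acid synthesis stood higher together in adapted livers. The list of SREBP-1c and ChREBP targets had a mean shift of +0.25, with 20 of 22 measured members up and 8 past an adjusted p of 0.05 adjusted over the list alone, against 0 over all genes tested. Its camera adjusted p was 1.19e-08, and it was the only list to pass with an estimated correlation, at an adjusted p of 0.031. Every adapted liver had a higher list mean than every control (exact permutation p = 0.0048, the smallest possible, and 0.238 after adjustment over the lists). Besides Acss2 and Acly, the leading members were Fasn, the fatty acid synthase, at +0.55 (adjusted p = 0.264) and Elovl6, which elongates its product, at +0.61 (adjusted p = 0.297). The mean shift was +0.33 in shRNA 1 livers and +0.17 in shRNA 2 livers, a difference of 0.16 (camera adjusted p = 0.00167, adjusted p = 0.213 with an estimated correlation), a call lost without shRNA 1 replicate 1.

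Camera with its preset correlation called 14 of the 50 lists tested, 11 higher and 3 lower, but only the lipogenic list passed with an estimated correlation. In fry 13 of the 14 did not pass; lipogenesis did, as did the gallbladder and mucous epithelium list (fry adjusted p = 0.0364, camera adjusted p = 0.573), which holds Ctse and had 4 of 6 members down. Of 100 splits of the 10 arrays into groups of the same sizes, the real one included, 9 reached 14 lists, and the median over the other splits was 8. The 13 lists below are therefore described with both p-values. Cholesterol synthesis had a mean of +0.18 with 18 of 19 members up (camera adjusted p = 2.35e-05, adjusted p = 0.426 with an estimated correlation), led by Pmvk (+0.28), Fdps (+0.37), Nsdhl (+0.35) and Fdft1 (+0.32). Without control replicate 4 the mean of this list was +0.11. Gluconeogenesis and glycogen had +0.16 with 15 of 19 up (adjusted p = 2.56e-04 and, with an estimated correlation, adjusted p = 0.411). There Ugp2, which makes UDP-glucose, was at +0.33, Got1 at +0.49 and G6pc, the catalytic subunit of glucose-6-phosphatase, at +0.58. The TCA cycle had +0.11 with 19 of 20 up (adjusted p = 2.16e-04 and, with an estimated correlation, adjusted p = 0.411), and Idh3b stood at +0.24 and Mdh2 at +0.19. Urea cycle and amino acid catabolism had +0.07 with 21 of 26 up (adjusted p = 0.0205 and, with an estimated correlation, adjusted p = 0.411), a call lost under settings that included leaving out control replicate 3 or 4, shRNA 1 replicate 2 or shRNA 2 replicate 3, quantile normalization, the mean of a gene's clusters and a clock covariate. The mean of this list was +0.15 in shRNA 1 livers and 0.00 in shRNA 2 livers, and that of gluconeogenesis and glycogen +0.26 and +0.06. Camera did not call either in shRNA 2 livers. In the same order, cholesterol synthesis had +0.14 and +0.21 and the TCA cycle +0.14 and +0.09.

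Sex-biased and drug-metabolising genes gave the largest mean shifts. Male-biased liver genes had a mean of -0.57 with 0 of 17 members up (camera adjusted p = 1.80e-09, adjusted p = 0.411 with an estimated correlation), including Mup21, Nudt7 (-0.57), Mup20 (-0.40) and the complement component C6 (-0.80). Without shRNA 2 replicate 3 the mean of this list was -0.34 and C6 stood at -0.53. Female-biased genes had +0.87 with 12 of 13 up (adjusted p = 2.48e-05 and, with an estimated correlation, adjusted p = 0.426). Cyp2b9 was at +3.70 with a standard error of 0.98, Slc22a26 at +2.30, Abcd2 at +0.82 and Fmo2 at +0.71, none of them past the threshold. CAR and PXR targets, the enzymes induced by foreign compounds, had +0.45 with 19 of 23 up (adjusted p = 8.15e-07 and, with an estimated correlation, adjusted p = 0.411), led by Gstt3 (+0.92), Gstt1 and Sult1d1 (+0.54), with Cyp2b9 a member of both lists. As fixed, the female-biased and the CAR and PXR lists also share Cyp2b13, so their shifts are not independent. The mean without the shared genes was not computed, and Cyp2b9, at +3.70, is far above both list means and raises them. By line the CAR and PXR mean was +0.63 in shRNA 1 livers and +0.27 in shRNA 2 livers. The spread within groups was wide: the male-biased mean of shRNA 2 replicate 3 was -1.43 against -0.03 and -0.18 in the other two shRNA 2 livers, and control replicate 4 stood at -0.42 against -0.01 to 0.28 in the other controls. Exact permutation p-values of the list means were 0.0524 for male-biased, 0.0333 for female-biased and 0.0381 for CAR and PXR genes, and each was 0.298 after adjustment.

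**Figure D2:**
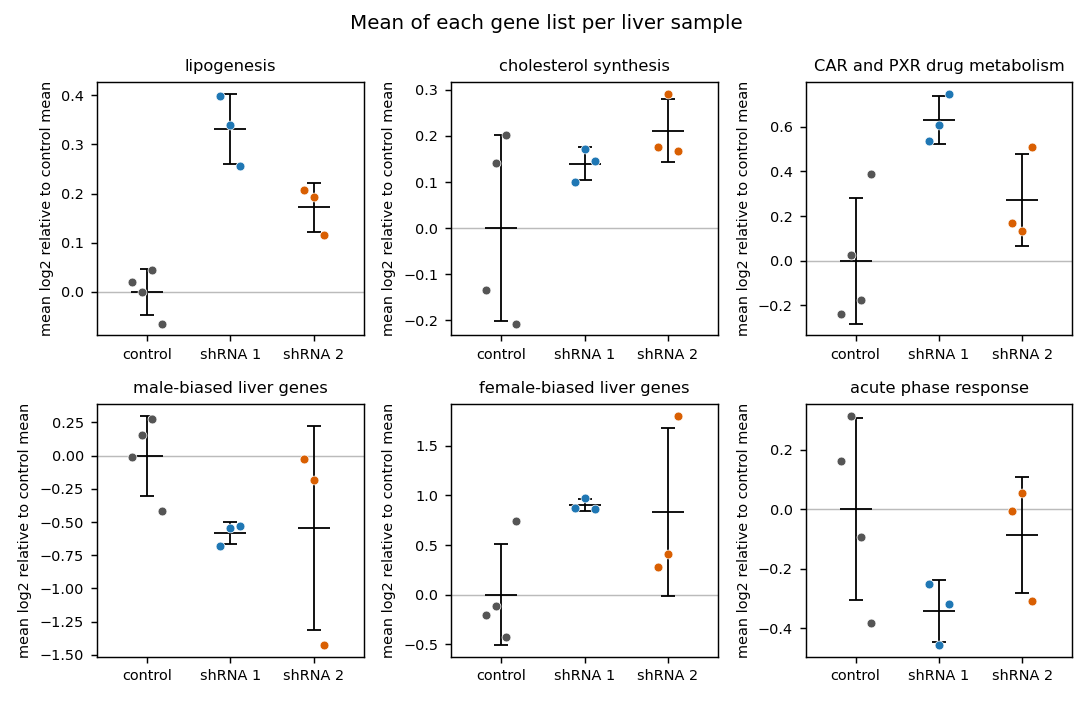
Mean log2 expression of the members of 6 gene lists relative to the control mean (y axis) in each liver sample by group (x axis); points are samples, horizontal bars are group means and error bars are 1 SD (n = 4, 3 and 3), with a grey line at 0. For lipogenesis all 6 adapted livers lie above all 4 controls, whereas for the sex-biased lists shRNA 2 replicate 3, at -1.43 and 1.80, lies apart from the other shRNA 2 livers.

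Antioxidant genes, the system nearest to the knocked-down enzyme, showed small differences. NRF2 targets, the genes induced by oxidative and electrophilic stress, had a mean of +0.14 with 20 of 28 up and 6 higher adjusted over the list alone (camera adjusted p = 8.86e-04, adjusted p = 0.411 with an estimated correlation). The leading members were Gstm3 (+0.71), Ces1g (+0.46), Pgd (+0.49) and Gsta3 (+0.32), of which Pgd belongs to the NADPH-making pentose phosphate pathway. The list mean was +0.28 in shRNA 1 livers and -0.01 in shRNA 2 livers. Antioxidant enzymes had +0.08 with 19 of 27 up (adjusted p = 0.0110 and, with an estimated correlation, adjusted p = 0.452), a call lost without control replicate 1; Glrx was at +0.39 and the mitochondrial peroxiredoxin Prdx3 at +0.24.

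The mitochondrial lists named next did not pass in adapted against control. Complex I had a mean of +0.04 (camera adjusted p = 0.260), complexes II to IV +0.06 (0.154), the ATP synthase 0.00 (0.746), mitochondrial ribosomal proteins +0.03 (0.567), mitochondrial chaperones and proteases -0.02 (0.746) and mitochondrial dynamics +0.05 (0.260). Control replicate 4 was the lowest control for complex I (-0.10), complexes II to IV (-0.08), ribosomal proteins (-0.11) and dynamics (-0.08), so these small means depend in part on that sample. Biogenesis and mtDNA maintenance had a mean of +0.02 but a median of -0.02 (0.958) with 10 of 22 members up, although Ppargc1a, the coactivator PGC-1 alpha, was at +0.59 (adjusted p = 0.264) and passed adjusted over the list alone. The mtDNA-encoded genes were not measured by a cluster of a single gene. ATF4 targets, a read-out of mitochondrial stress, had -0.13 (0.0723), with Mthfd2 at -0.83 and Psat1 at -0.41. Without control replicate 4 the mean of this list was -0.05 and Psat1 stood at -0.26. Within single lines, complexes II to IV passed in shRNA 1 livers at +0.08 (camera adjusted p = 0.0406, adjusted p = 0.555 with an estimated correlation), a call lost without any 1 of control replicates 1, 2 and 4 and shRNA 1 replicates 1 and 3. ATF4 targets passed in shRNA 2 livers at -0.17 (camera adjusted p = 0.0466, adjusted p = 0.841 with an estimated correlation), a call lost without control replicate 4 (mean -0.09), shRNA 1 replicate 2 or any 1 of the shRNA 2 livers. PPAR-alpha targets of fatty acid oxidation had +0.01 (0.989), and Fgf21, a stress-induced hormone of the liver, was at -0.94 (adjusted p = 0.504).

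Among defence and growth lists, interferon-stimulated genes had a mean of +0.16 with 25 of 29 up (camera adjusted p = 2.48e-05, adjusted p = 0.411 with an estimated correlation), led by Xaf1 (+0.40) and Oasl2 (+0.40). By line the mean was +0.26 in shRNA 1 livers and +0.06 in shRNA 2 livers. Acute phase genes had -0.22 with 19 of 23 down (adjusted p = 1.31e-04 and, with an estimated correlation, adjusted p = 0.452), led by Apcs, serum amyloid P, with Itih3 at -0.19 and Hp at -0.23. The mean of this list was -0.11 without control replicate 2 and -0.34 without control replicate 4. By line it was -0.34 in shRNA 1 livers and -0.09 in shRNA 2 livers. The cell cycle list had +0.14 with 25 of 28 up (adjusted p = 0.00162 and, with an estimated correlation, adjusted p = 0.555), with Tyms at +0.30 and Rrm2 at +0.33. Settings that lost this call included leaving out control replicate 4, shRNA 1 replicate 1 or shRNA 2 replicate 3 (mean +0.09 without the last) and a clock covariate. The unfolded protein response of the endoplasmic reticulum had -0.09 with 19 of 24 down (adjusted p = 0.00828 and, with an estimated correlation, adjusted p = 0.555), with Syvn1 at -0.43. It was lost, among other settings, without control replicate 3, shRNA 1 replicate 1 (mean -0.06) or shRNA 2 replicate 3, and with a clock covariate. In shRNA 1 and shRNA 2 livers the cell cycle mean was +0.09 and +0.20, and that of the unfolded protein response -0.06 and -0.12. Markers of liver cell types did not pass in adapted against control: hepatocytes stood at 0.00 (camera adjusted p = 0.958), macrophages at +0.10 (0.0977), sinusoidal endothelium at +0.08 (0.0757), stellate cells at +0.04 (0.567), T and NK cells at +0.18 (0.138) and B cells at a mean of +0.05 with a median of -0.05 (0.765). Single samples weighed on some of these means. The highest macrophage values were those of shRNA 2 replicate 1 (+0.32) and control replicate 1 (+0.16). For stellate cells they were those of shRNA 2 replicate 3 (+0.20) and control replicate 4 (+0.16). Pericentral hepatocyte markers were at -0.01 (0.979) and periportal ones at +0.02 (0.925).

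Each hairpin was then set against the same 4 controls. In shRNA 1 livers 0 genes passed in limma, with 1050 at an unadjusted p under 0.05. The smallest adjusted p was 0.0520, for Acss2 at +0.76 (10.44 ± 0.02, SD, n = 3, against 9.68 ± 0.14, n = 4). Just behind it, at an adjusted p of 0.0525, were Gstm3, a glutathione transferase (+1.35), Xaf1 (+0.68), Xdh, xanthine dehydrogenase (+0.64), Fgl1, a secreted hepatocyte protein (-0.76), Tspan33 (-0.82) and Apcs (-0.76). Trim12a was at +0.75 (adjusted p = 0.059), Pdilt at -0.82 (0.0609) and Adh6-ps1 at -0.91 (0.071). The count of 0 moved with ordinary settings, to 8 with quantile normalization, 19 with array weights and 30 with an intensity trend and robust prior, to 2 without control replicate 1, 9 without control replicate 4, 1 without shRNA 2 replicate 2 and 11 without shRNA 2 replicate 3. Camera called 16 lists, 14 higher and 2 lower, and 3 of 35 splits of the 7 arrays, the real one included, gave as many. Lipogenesis alone passed with an estimated correlation (adjusted p = 0.0210), and 5 of the 16 passed fry. With each array left out in turn 12 of the 16 kept their calls throughout. NRF2 targets had +0.28 with 23 of 28 up, and adjusted over the list alone 12 were higher and 1 lower (camera adjusted p = 4.64e-09, adjusted p = 0.0820 with an estimated correlation). Gluconeogenesis and glycogen had +0.26 with 17 of 19 up (adjusted p = 1.16e-07 and, with an estimated correlation, adjusted p = 0.102) but +0.17 without shRNA 1 replicate 1, and CAR and PXR targets +0.63 with 21 of 23 up (adjusted p = 9.26e-11 and, with an estimated correlation, adjusted p = 0.107). Interferon-stimulated genes had +0.26 with 26 of 29 up (adjusted p = 5.77e-09 and, with an estimated correlation, adjusted p = 0.189), and acute phase genes -0.34 with 19 of 23 down (adjusted p = 1.30e-06 and, with an estimated correlation, adjusted p = 0.392). Markers of sinusoidal endothelial cells stood at +0.13 with 9 of 12 up (adjusted p = 0.00890 and, with an estimated correlation, adjusted p = 0.346), a call lost without control replicate 3 or shRNA 1 replicate 1. Camera also called male-biased genes (-0.58), female-biased genes (+0.90), urea cycle genes (+0.15), TCA cycle genes (+0.14), cholesterol synthesis (+0.14), AHR targets (+0.27), antioxidant enzymes (+0.10) and glucocorticoid targets (+0.13). With an estimated correlation their adjusted p-values were 0.107 to 0.555. The cholesterol call was lost without control replicate 1 or 4 (mean +0.07 without the latter). The glucocorticoid call was lost without shRNA 1 replicate 1 (mean +0.04), control replicate 1 or 3, or shRNA 2 replicate 2.

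In shRNA 2 livers 1 gene passed in limma, Ctse, higher by 2.30 on the log2 scale (standard error 0.08, adjusted p = 6.68e-08), in 3 of 3 livers. The control mean, 3.97, was below every array's median and was not shown to lie above background, so this difference is read as a lower bound. The next genes by rank did not pass: Arrdc4 (+0.69, adjusted p = 0.215), Pm20d1 (+0.67), Pde7b (+0.53) and Tmem163 (+0.55) on the higher side, and Cdc34 (-0.65), Adh6-ps1 (-0.94), U2af1 (-0.58), the phosphatase Dusp1 (-0.62) and Gigyf1 (-0.47) on the lower side. With a filter at the 60th percentile of level Ctse was no longer tested and 0 genes passed. Without control replicate 1 there were 3 calls and without control replicate 4 there were 2, each including Ctse. Camera called 10 lists, 6 higher and 4 lower, of which 0 passed with an estimated correlation or in fry, where the gallbladder and mucous epithelium list passed instead. With each array left out in turn, 2 of the 10 calls held throughout, lipogenesis and cholesterol synthesis, and 8 were lost in at least 1 fit. Of the splits of these 7 arrays, the real one included, 6 of 35 gave as many. Lipogenesis had +0.17 (camera adjusted p = 4.22e-04, adjusted p = 0.295 with an estimated correlation) and cholesterol synthesis +0.21 with 18 of 19 up (adjusted p = 1.41e-05 and, with an estimated correlation, adjusted p = 0.841). The cell cycle list had +0.20 with 26 of 28 up (adjusted p = 4.22e-04 and, with an estimated correlation, adjusted p = 0.841), macrophage markers +0.15 with 12 of 14 up (adjusted p = 0.00713 and, with an estimated correlation, adjusted p = 0.841) and the unfolded protein response -0.12 with 21 of 24 down (adjusted p = 0.00341 and, with an estimated correlation, adjusted p = 0.841). The other called lists were male-biased genes (-0.55), female-biased genes (+0.83), TCA cycle genes (+0.09), immediate early genes (-0.19) and ATF4 targets (-0.17), each at an adjusted p of 0.841 with an estimated correlation. Leaving out shRNA 2 replicate 3 ended the calls of male-biased genes (mean -0.10), female-biased genes (+0.34), the cell cycle list (+0.09) and the unfolded protein response (-0.07). The macrophage call was lost without shRNA 2 replicate 1 (+0.06) or control replicate 3, and its mean was +0.23 without shRNA 2 replicate 3. The TCA cycle call was lost without control replicate 4 (+0.06) or shRNA 2 replicate 2. The call of immediate early genes was lost without control replicate 1, shRNA 1 replicate 2 or shRNA 2 replicate 1 or 2 (-0.12 without the last), and their mean was -0.30 without shRNA 2 replicate 3.

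The shRNA 1 and shRNA 2 livers were also compared with each other, which tests a difference between the groups, whether it comes from hairpin, cohort or line. In limma 2 genes passed: Ctse, lower in shRNA 1 than in shRNA 2 livers by a log2 difference of -2.40 (adjusted p = 8.72e-08), and Dusp1, a stress-induced phosphatase of MAP kinases, higher by 0.99 (adjusted p = 0.0350). The Ctse mean in shRNA 1 livers, 3.87, was not shown to lie above background either, so the size of its difference is read as a lower bound. Dusp1 was at 8.49 ± 0.16 (SD, n = 3) in shRNA 1, 7.50 ± 0.09 (n = 3) in shRNA 2 and 8.12 ± 0.18 (n = 4) in control livers, and with each array left out in turn it kept its call in 1 of 10 cases, without control replicate 4, where 4 genes passed, whereas Ctse kept its call in 10 of 10. Gstm3 (+1.28), Csad, which makes hypotaurine (+2.01), Xdh (+0.64), Cep85l (+0.87) and Fgl1 (-0.78) had adjusted p-values between 0.0821 and 0.0993, and Stap1 (-0.80), Adamdec1 (-0.62) and Adgrf1 (-0.78) lay at 0.168 to 0.233. Camera called 10 lists, of which 0 passed with an estimated correlation and 1, NRF2 targets, in fry, where the gallbladder and mucous epithelium list passed too. NRF2 targets were higher in shRNA 1 than in shRNA 2 livers by 0.28 with 24 of 28 members (camera adjusted p = 4.55e-10, adjusted p = 0.108 with an estimated correlation).

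**Figure D3:**
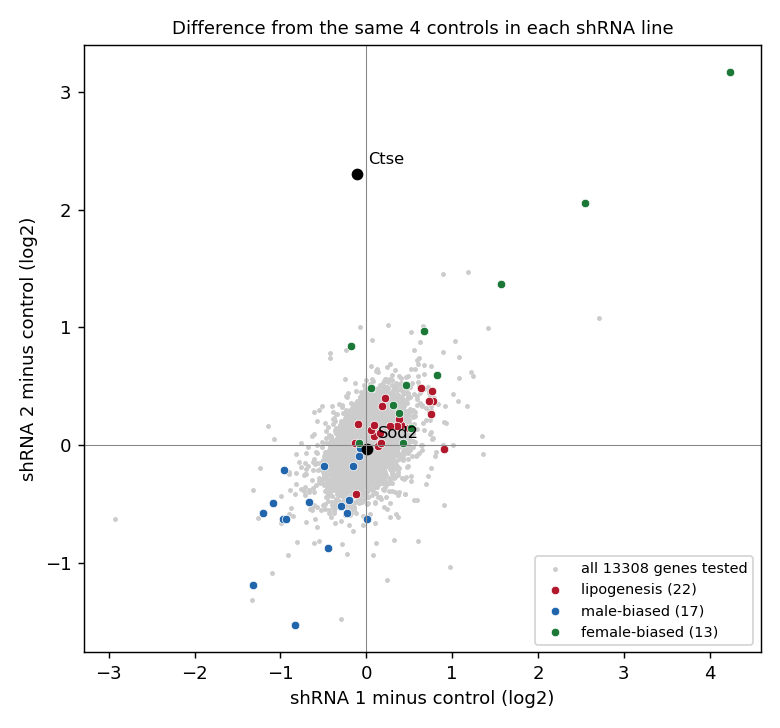
Log2 difference from the same 4 controls in shRNA 1 livers (x axis) and shRNA 2 livers (y axis) for each of 13308 genes, with 3 gene lists coloured and Ctse and Sod2 in black. Ctse lies at -0.10 and 2.30, Sod2 at 0.01 and -0.03, and most male-biased genes lie in the lower left and most female-biased genes in the upper right.

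The differences from control of each line were also compared with each other. Across genes, which are not independent replicates, the log2 differences correlated at r = 0.512, against a mean of 0.428 (range 0.401 to 0.456 over 50 runs with independent genes) simulated for groups without any effect that share 4 controls. Without shRNA 2 replicate 3 r was 0.436, but no value without effect was simulated for those group sizes, so it cannot be set against 0.428. The covariance was 0.0167 against 0.00844 simulated, a difference of 0.00827. With the controls split 2 and 2, so that no control was shared, r lay between 0.0506 and 0.271 over 6 splits, with a mean of 0.143. At an unadjusted p under 0.05, 272 genes moved the same way in both lines, 162 higher and 110 lower, and 9 moved in opposite directions. The simulation without effect gave a mean of 122 in the same direction (range 102 to 149 over 20 runs), and lists independent of each other would share 25.2 higher and 15.3 lower genes. The simulated genes were independent of each other and without effect, where 665.4 per line would fall under that p by chance. The real lines had 1050 and 1011, and larger lists share more genes by themselves. Lists taken as independent ignore the shared controls. Neither number therefore tests whether the lines agree beyond chance.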

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

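The tests of mucosal tissue, litter cohort, a female liver and harvest time were chosen only after the results they address were seen. The tests on other splits of the samples and on the neighbours of Ctse were set before their outcome was known.

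Ctse differed between the lines by -2.40 on the log2 scale (shRNA 1 minus shRNA 2), a size read as a lower bound since the low values were not shown to lie above background. The 3 shRNA 2 livers stood at 6.24 to 6.33 and the other 7 livers at 3.79 to 4.03. Stomach or gallbladder mucosa in those samples is argued against: the median of the 8 other mucous markers was -0.11 in shRNA 2 minus control (standard error 0.06), and the highest was 0.09. A cohort effect is also argued against for this gene, since all 4 controls, which came from both cohorts, lay on the shRNA 1 side of the midpoint. A chromosome stretch from another strain, carried along with the shRNA 2 construct or its stem cells, may account for it and stays open: 12.5% of the 40 neighbouring genes had an unadjusted p under 0.05, the 91.3rd percentile of such windows, which lies between the bounds set for and against. As a count, 1 gene in shRNA 2 against control was reached by 3 of 35 splits (highest other 3), so chance is not excluded for the count, and an effect of the hairpin itself was not tested.

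Dusp1 differed between the lines by 0.99 on the log2 scale. Together with Ctse it makes 2 genes; the 10 splits of 6 arrays are too few for a share under 0.05, with 1 split, the real one, reaching 2 and the highest other at 0. For Dusp1 itself the controls were at 8.12 ± 0.18 (SD, n = 4) and the shRNA 2 livers at 7.50 ± 0.09 (SD, n = 3). Cohort alone would have put the 3 controls from the shRNA 2 cohort near the latter. This argues against cohort as the whole cause for this gene, and a part for it stays open. Across genes, whether cohort rather than hairpin separates the lines cannot be told apart: over the genes with an unadjusted p under 0.05 between the lines, 1 of 4 controls lay on the shRNA 1 side, as 1 control from that cohort could give. That reading fails its own check, because shRNA arrays left out of choosing the genes fell on the side of their own line in only 3 of 6 cases. The labels do not say which control came from which cohort.

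In adapted livers male-biased genes had a mean shift of -0.57, female-biased genes +0.87 and lipogenic genes +0.25. A female liver among the arrays is argued against, since Xist stayed within 2.61 to 3.49 and Eif2s3y, on the Y chromosome, within 8.01 to 8.52 over the 10 arrays (smallest gap 4.52), so no array stood apart. For lipogenesis the shift kept 0.973 of its size with the clock covariate and at least 0.908 with any array left out, which met the condition set against harvest time. The clock score, however, differed by 0.47 between adapted and control livers over a range of -1.12 to 1.70 (exact permutation p = 0.552). A covariate so weakly tied to group could change the shift little, so the kept share by itself decides little. Livers of similar clock score can be compared instead. Among those with a negative score, the list mean was -0.06 to 0.04 in controls and 0.19 to 0.34 in adapted livers. With a positive score it was 0.02 in control replicate 1 and 0.12 to 0.40 in adapted livers. This argues against harvest time, as far as the score reads it, for this list. How well the score tracks harvest time was not tested. Harvest time stays open for the male-biased and female-biased lists, which kept 0.882 and 0.960 but as little as 0.594 and 0.740 with an array left out. Chance is not excluded for the number of lists: 9 of 100 splits reached 14, and the highest other was 17. An effect of the knockdown stays among the open explanations, untested, as do litter and pubertal stage.

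For the next 3 counts, chance is likewise not excluded. In adapted against control 5 of 100 splits reached 1 gene (highest other 4). In shRNA 1 against control 3 of 35 splits reached its 16 lists (highest other 16). In shRNA 2 against control 6 of 35 splits reached its 10 lists (highest other 15). For shRNA 1 against shRNA 2 the 10 splits are too few for a share under 0.05, with 10 lists in the real split, 10 in the highest other and 2 splits reaching that number. The count of 0 genes in shRNA 1 against control has no such test, since 35 of 35 splits reach 0 whatever the data (highest other 4).

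Between the lines 10 lists differed in camera at its preset correlation, and 0 passed with an estimated one. Higher in shRNA 1 livers were NRF2 targets (0.28), gluconeogenesis and glycogen (0.20), lipogenesis (0.16), CAR and PXR targets (0.36), glucocorticoid targets (0.29), interferon-stimulated genes (0.20), cytosolic heat shock genes (0.26) and urea cycle genes (0.15). Lower in shRNA 1 livers were acute phase genes (-0.26) and macrophage markers (-0.11). Calls were lost for macrophage markers without shRNA 2 replicate 1 (-0.02) or shRNA 1 replicate 1 or 2 (-0.06 without the latter), and for lipogenesis, glucocorticoid targets and gluconeogenesis (0.11) without shRNA 1 replicate 1. Without shRNA 2 replicate 3 the values were 0.14 for glucocorticoid targets, 0.12 for interferon-stimulated genes, 0.17 for heat shock genes and -0.19 for macrophage markers.

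One control lay far from the other 3 in 14 of 294 sets of 4 control values, where chance gives about 1 in 20, or 14.7. The gap to the nearest other control, as a share of the range, was 0.882 for Acss2, 0.883 for Gsta3, 0.841 for Arg1 and 0.870 for the pancreatic exocrine list, all control replicate 1. It was 0.862 for Spg7 and 0.841 for Epcam, both control replicate 2. For control replicate 4 it was 0.854 for Dhrs7, 0.971 for Acot3, 0.840 for Gbe1, 0.938 for Sgk1, 0.912 for Mup20, 0.868 for Fmo2, 0.869 for Plin1 and 0.934 for Acta1.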

How the results depend on the processing

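The clock covariate and the fit without 2 arrays were chosen after seeing the data. A value counted as reversed where its sign changed and it passed the threshold in either fit. Of 7169 values of 303 single genes and lists, 6931 stayed on their side of the threshold and 0 reversed. Of the rest, 62 no longer passed and 176 newly passed. Most of these results did not pass in the main fit, so staying mostly means staying uncalled, and only a value with a call could reverse. For the 14 lists called in adapted against control, 23 alternatives were run. Of these, 11 ended the urea cycle call, 8 the cell cycle call and 7 that of the unfolded protein response. Any other list lost its call in at most 3. Sod2 did not pass under any alternative run, with differences of -0.07 to 0.02. The cause of each change below was not tested unless stated. Adapted against control (1 gene) gave 0 with the 60th percentile filter, which leaves Ctse untested, 0 with 2 groups, where the spread between the lines enters the error, 6 with trend and robust prior, 2 at an adjusted p of 0.10, 62 at unadjusted p with 1.5-fold, and 1 to 3 with an array left out (3 without control replicate 1, 2 without control replicate 4). The shRNA 1 count (0) was 8 with quantile normalization, 9 with median centring, 15 with the 60th percentile filter, 7 with the mean of clusters, 19 with array weights, 30 with trend and robust prior, 2 with the clock covariate, 20 at 0.10, 127 at unadjusted p with 1.5-fold, and 0 to 11 with an array left out (2 without control replicate 1, 9 without control replicate 4, 1 without shRNA 2 replicate 2, 11 without shRNA 2 replicate 3). The shRNA 2 count (1) was 0 with the 60th percentile filter, 64 at unadjusted p with 1.5-fold and 1 to 3 with an array left out (the same controls). The count between the lines (2) was 1 with quantile normalization, median centring, the 60th percentile filter, every cluster or the clock covariate, 6 with array weights, 7 with trend and robust prior, 8 at 0.10, 92 at unadjusted p with 1.5-fold and 1 to 4 with an array left out (2 without control replicate 1, 4 without control replicate 4, 1 without any other). Without control replicate 4 and shRNA 2 replicate 3 the counts were 3 (adapted), 35 (shRNA 1) and 5 (between lines); these arrays were picked for their sex-biased values, so this is no independent evidence. Cell cycle, urea cycle and unfolded protein response lists lost their calls there too. Of the 14 lists, 1 passed with an estimated correlation; fry passed 2, of which 1 was among the 14. The correlation of the lines' differences (0.512) was 0.436 to 0.574 with an array left out. The value without any effect changes with the group sizes and was not simulated for these fits, so the range does not show stronger or weaker agreement. No background level is given in the sources used here, so which genes lay near it was not determined; the control mean of Ctse, 3.97, was just below the level filter at 3.98.

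Replicate numbers are shared between groups, and deviations of samples with the same number correlated at -0.250 to 0.267. Samples with different numbers were not compared in this way, so whether equal numbers mark a shared litter or batch is not settled. With the replicate block, in which control replicate 4 stands alone and drops out, the count between the lines was 4 and the correlation 0.566; other counts of genes did not move. The cell cycle and urea cycle lists lost their calls in adapted against control under this block.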

Other observations

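Gene families were grouped by symbol and tested after the data were seen, and of 200 families 2 passed camera in adapted against control. Annexins (Anxa), calcium-dependent membrane-binding proteins, had a mean of +0.19 with 9 of 9 members up (camera adjusted p = 0.00609). Aldehyde dehydrogenases (Aldh) had +0.13 with 16 of 17 up (adjusted p = 0.0240). Neither passed with an estimated correlation, at an adjusted p of 0.797 for both.

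Some genes of the sex-biased and growth hormone lists had a wide range within groups. Cyp2b9, a female-biased cytochrome, was at 3.64 to 5.95 in control replicates 1 to 3, 9.35 in control replicate 4, 9.80 to 10.14 in shRNA 1 livers and 6.90 to 10.45 in shRNA 2 livers. Slc22a26 was at 7.35 in control replicate 4 against 4.39 to 5.26 in the other controls, and at 9.42 in shRNA 2 replicate 3. Bcl6, a repressor in the growth hormone pathway, ranged from 5.31 to 8.42 and Onecut1 from 6.47 to 9.57 over the 10 livers. Csad, which is outside these lists, was at 9.52 in control replicate 4, near the shRNA 1 livers at 9.62 to 9.73, and at 7.93 to 8.72 in the other controls. These values do not assign the control to a cohort.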
